A study of Artemisia annua with 12 samples.

How the data were processed

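Leaves of Artemisia annua, the plant from which the antimalarial artemisinin is extracted, were profiled by RNA sequencing in 12 libraries. Six-week-old seedlings of a cultivar bred for high artemisinin content stood under additional narrowband UV-B lamps, and leaves were harvested after 0, 2, 4 and 6 h. Each of the 4 harvests has 3 libraries, and each library is a mix of leaves from 3 seedlings, per the labels' protocols, which call the 3 libraries biological repeats. The p-values below measure the spread between these libraries. The labels give no library from seedlings kept without UV-B until 2, 4 or 6 h, so hours of UV-B and hour of the day cannot be told apart in any comparison.

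The authors deposited one table of normalised expression signal, with 1 row for each of 63226 gene identifiers and 1 column per library, rounded to 2 decimals. The table's header names no unit. Library totals lie between 851404 and 868133, and the smallest listed values differ from gene to gene. The values therefore behave like TPM of which a part lies outside the listed genes, or like FPKM, and the data do not settle which; both divide by gene length and by a library total. The submitters' processing notes name HISAT2 2.1.0, Salmon and DESeq without their roles; the genome build is not given in the sources used here. Column names carry the group and the replicate number of the sample titles, and no column of another sample was present (0 columns).

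Read depth is not stated and is unknown here. The values of genes listed in only 2 to 4 libraries were examined for the worth of 1 read, but an estimate of relative depth needed a bound of 1.5 on their ratio, which rules out larger differences from the start, so none is given. No count was recovered and no count model was run, although the design written in advance also provided for counts.

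Values were taken as log2(value + 1), and all log2 changes, the minimum folds of 2 and 8 and the tests are on this scale, which understates changes of genes with low values. Folds printed for single genes are ratios of mean values without a pseudocount, and so differ from their log2 changes. Where a gene is listed at 0 in a whole harvest, the pseudocount sets the size of its log2 change, which is no bound. Genes with a value of at least 1 in at least 3 libraries were tested, which left 25841; 21712 genes were listed at 0 in every library. One limma model (limma 3.58.1 in R 4.3.3, with a trend of variance on level and robust estimation) held all 12 libraries in 4 groups, and each pair of harvests was a contrast. A moderated F test covered the 3 contrasts against 0 h together. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, and all adjusted p-values below come from this limma model. Summary values of libraries were compared with an exact two-sided permutation test, whose smallest p with 3 libraries against 3 is 0.1.

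The procedure was tested on simulated values for the same 25841 genes, with the fitted spread of each gene and 200 genes changed at 2 h against 0 h, 50 at each of 4 sizes. It called 6% of the genes changed by 0.25 on the log2 scale and 50% of those changed by 0.5. Of those changed by 1 and by 2 it called 76% and 98%. Of its 124 calls, 9 were false. In the data 14722 genes were called at 2 h, which makes the adjusted threshold less strict than with 200 changed genes. The shares recovered in the simulation therefore do not carry over to the data.

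Before the data were examined, 27 gene lists (artemisinin and flavonoid synthesis, light signalling, DNA repair, the circadian clock, photosynthesis, markers of trichomes, vascular and guard cells, and others) were fixed as search terms for gene names. The deposited table pairs no identifier with a name and no annotation was at hand, so none of these lists was tested. The rule for named genes then called for the 2 identifiers with the largest rise and the 2 with the largest fall at 6 h against 0 h on the log2(value + 1) scale, and only these are printed. Genes are otherwise described in groups, by direction, size, time course and abundance; the abundance groups rest on the mean over all 12 libraries. The minimum fold of 2 was among the choices made in advance; the time-course groups, the abundance groups and the groups of genes present at one harvest and near 0 at another were chosen after the values were seen. A gene was called present in a harvest at 5 or more in all 3 libraries and near 0 at 0.1 or less in all 3.

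The model has no replicate term. Alternatives were a replicate block, pseudocounts of 0.1 and 5, no filter, median-ratio scaling of the libraries, limma without trend or robust estimation, models of only the 2 harvests compared, a minimum fold of 2, and leaving out each library in turn. A rescaling without the 10 genes of highest mean value was added after seeing the data.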

Results

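The data comprised normalised expression values of leaf RNA from Artemisia annua seedlings after 0, 2, 4 and 6 h under UV-B lamps, with 3 libraries per harvest. Genes with a value above 0 numbered 31992 ± 225 (SD, n = 3) at 0 h, 33117 ± 332 at 2 h, 32736 ± 188 at 4 h and 32507 ± 287 at 6 h, where the libraries overlapped those at 0 h (exact permutation test, two-sided p = 0.2; p = 0.1 at 2 and 4 h). Genes at a value of 1 or more numbered 22251 ± 79.5 (SD, n = 3) at 0 h, 23488 ± 79.6 at 2 h, 23557 ± 29.7 at 4 h and 23546 ± 103 at 6 h. Every exposed library had more such genes than every library at 0 h (exact permutation test, two-sided p = 0.1 for each harvest, the smallest that 3 libraries against 3 allow). The median log2 change of the tested genes against 0 h was 0.13 to 0.21, and such a lift alone can carry genes past a fixed value of 1. These numbers were not computed after rescaling.

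Libraries of the same harvest lay close together. Over the 25841 tested genes, pairs of libraries within a harvest correlated at r = 0.975 to 0.981 on the log2 scale, a correlation across genes, which are not independent replicates. Libraries at 0 and 2 h correlated at 0.884 to 0.889, those at 2 and 4 h at 0.906 to 0.913, and those at 4 and 6 h at 0.969 to 0.971. For genes with a mean above 1000, the median coefficient of variation of 3 libraries was 1.39% at 0 h, 1.89% at 4 h and 1.78% at 6 h. It was 4.4% at 2 h, where replicate 1 stood apart: for such genes it spread by 7.11% and 8.47% against the other libraries of that harvest, which spread by 2.03% between themselves. Genes at a mean of 1 to 5 had a median coefficient of 16% to 16.8%. With a spread this small, differences well under 2-fold passed the test, so counts with a minimum fold are given beside those without.

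**Figure D1:**
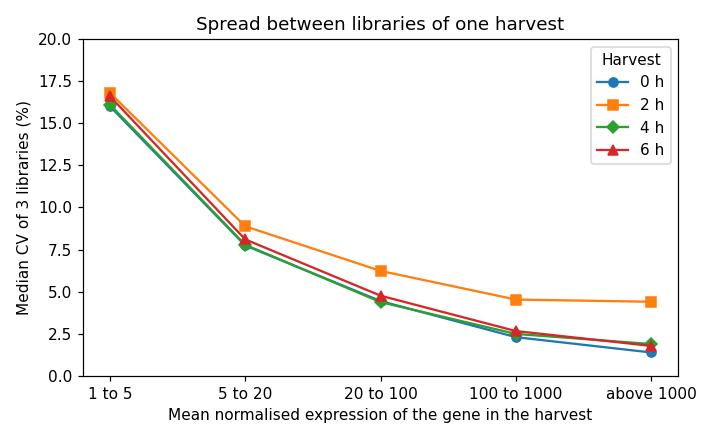
Median coefficient of variation (percent) of the 3 libraries of each harvest, by the mean normalised expression of the gene; each line is a harvest (0, 2, 4 or 6 h). The spread falls from about 16% at the lowest values to 1.39% at 0 h above 1000, and the 2 h harvest stays at 4.4%.

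The comparison of 2 h with 0 h asked which transcripts differed early, after 2 h under supplementary UV-B. At 2 h, 9344 genes had risen and 5378 had fallen among the 25841 tested, while 11119 did not pass the test. At least a 2-fold change was measured for 2658 of the genes that rose and 1221 of those that fell, and at least an 8-fold change for 211 and 51. The largest rise at 6 h on the log2(value + 1) scale, that of CTI12_AA522570, was already present at 2 h, with a value of 3.07 ± 1.27 (SD, n = 3) at 0 h and 1192 ± 149 at 2 h, a 388-fold rise in the mean value (change of 8.24 ± 0.20 SE on the log2(value + 1) scale, limma adjusted p = 2.24e-10). CTI12_AA422800 was listed at 0 in each library at 0 h and at 91.04, 81.39 and 103.58 in the 3 libraries at 2 h (log2 change 6.53 ± 0.101 SE, limma adjusted p = 1.39e-12). Which of these 2 genes rose more depends on the pseudocount, and with 0.1 it was CTI12_AA422800, whose log2 change at 2 h was 9.84 with a pseudocount of 0.1 and 4.27 with 5. Both genes with the largest falls at 6 h on this scale were already lower at 2 h. CTI12_AA498370 fell from 17206 ± 357 to 4824 ± 126 (SD, n = 3; log2 change -1.83 ± 0.243 SE, limma adjusted p = 0.000102), and CTI12_AA508840 from 177.7 ± 5.40 to 50.3 ± 8.57 (log2 change -1.81 ± 0.096 SE, limma adjusted p = 2.7e-08). What these 4 genes encode is not given by the deposited table.

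The values of 16092 genes (62.3%) did not overlap between the 3 libraries at 2 h and the 3 at 0 h, where chance gives 10%. Between 4 and 6 h the share was 29.2%. A shift shared by most genes can also separate the libraries of 2 harvests, so this share is not one of changed genes. The median log2 change of all tested genes was 0.13, and changes should be read relative to it: after median-ratio scaling of the libraries, 7483 genes were higher and 7131 lower, a share of 51.2% higher in place of 63.5%, with 2271 and 1600 genes at 2-fold or more. The 2-fold counts depend on the pseudocount; with 5 they were 1075 and 444, and with 0.1 they were 3926 and 1768. Without replicate 1 of the 2 h harvest, 8536 genes were higher and 5224 lower, of which 2617 and 1218 at 2-fold or more.

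At 4 h, 10848 genes were higher and 4662 lower than at 0 h, and 10331 did not pass the test. Changes of at least 2-fold comprised 3034 rises and 1323 falls, and changes of at least 8-fold 291 rises and 84 falls. Of the 3034 genes that had risen 2-fold or more, 2352 (77.5%) had also risen at 2 h, 1454 of them by 2-fold or more. A later group of 516 genes had not passed the test at 2 h and was higher at 4 h than at 2 h. Of the 1323 that had fallen 2-fold or more, 924 (69.8%) had fallen at 2 h as well, and 259 had not passed the test at 2 h and were lower at 4 h than at 2 h. CTI12_AA522570 stood at 1336 ± 50.8 (SD, n = 3), 435-fold above 0 h in mean value, and CTI12_AA422800 at 189.6 ± 3.98. CTI12_AA498370 had dropped to 6.94 ± 2.49, 2478-fold below 0 h in mean value (change of -11.14 ± 0.243 SE on the log2(value + 1) scale, limma adjusted p = 8.13e-11), and CTI12_AA508840 was listed at 0 in all 3 libraries (limma adjusted p = 2.33e-13).

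The median log2 change at 4 h was 0.21. Median-ratio scaling gave 7383 genes higher and 7261 lower (50.4% higher in place of 69.9%), with 2322 and 1834 at 2-fold or more. With a pseudocount of 5 the 2-fold counts were 1275 and 480; among these the later groups numbered 109 genes that rose and 53 that fell (705 and 459 with a pseudocount of 0.1), and 594 of the raised genes had also risen 2-fold or more at 2 h, or 2451 of 4346 with a pseudocount of 0.1.

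At 6 h, 10660 genes were higher and 4781 lower than at 0 h, with 3009 and 1254 at 2-fold or more and 303 and 87 at 8-fold or more. CTI12_AA522570 was measured at 1339 ± 23.4 (SD, n = 3), 436-fold above 0 h in mean value (log2 change 8.42 ± 0.20 SE, limma adjusted p = 1.53e-10), and CTI12_AA422800 at 157.5 ± 22.5 (log2 change 7.30 ± 0.101 SE on the log2(value + 1) scale, limma adjusted p = 3.38e-13; log2 change 10.61 with a pseudocount of 0.1 and 5.01 with 5). CTI12_AA498370 stood at 6.39 ± 1.96, 2694-fold below 0 h in mean value (log2 change -11.22 ± 0.243 SE, limma adjusted p = 7.81e-11). CTI12_AA508840 was again listed at 0 in all 3 libraries (limma adjusted p = 1.97e-13). The median log2 change was 0.20, and median-ratio scaling gave 7441 genes higher and 7284 lower (50.5% higher in place of 69%), with 2368 and 1789 at 2-fold or more. With a pseudocount of 5 the 2-fold counts were 1237 and 469.

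**Figure D2:**
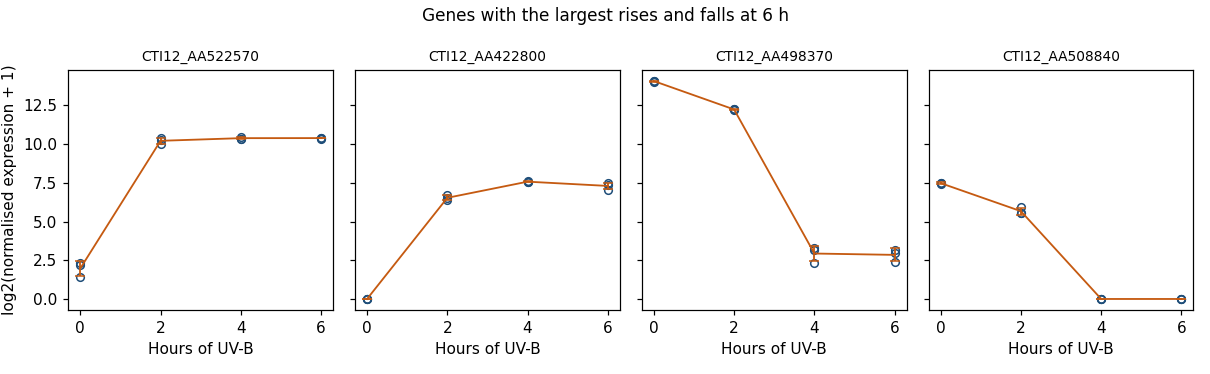
Normalised expression as log2(value + 1) against hours of UV-B for the genes with the largest rises (CTI12_AA522570 and CTI12_AA422800) and falls (CTI12_AA498370 and CTI12_AA508840) at 6 h on this scale; circles are libraries, and lines join harvest means with SD bars (n = 3). On this log scale most of each rise had taken place by 2 h and most of each fall took place between 2 and 4 h.

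Direct comparison of the harvests showed a second large change between 2 and 4 h and a small one afterwards. Between 2 and 4 h, 8031 genes rose and 5034 fell, with 1441 and 1341 at 2-fold or more. Median-ratio scaling gave 6335 rises and 6201 falls (50.5% higher in place of 61.5%) and turned the balance of the 2-fold changes, to 1199 rises and 1524 falls. CTI12_AA498370 fell by 9.30 on the log2 scale in this interval (limma adjusted p = 1.02e-09) and CTI12_AA508840 fell by 5.67 (limma adjusted p = 8.57e-12). As CTI12_AA508840 was listed at 0 at 4 h, the pseudocount sets the size of its change, which was -8.96 with 0.1 and -3.46 with 5. CTI12_AA422800 rose by 1.04 (limma adjusted p = 6.83e-06), and the log2 difference of CTI12_AA522570 was 0.17 ± 0.20 SE (limma adjusted p = 0.506). Between 4 and 6 h, 1148 genes rose and 1413 fell, and 107 and 51 of them changed 2-fold or more, or 39 and 13 with a pseudocount of 5 and 168 and 101 with one of 0.1. None of the 4 named genes passed the test in that interval. Between 2 and 6 h, 7718 genes rose and 5180 fell, with 1416 and 1277 at 2-fold or more, a balance that median-ratio scaling turned to 1195 and 1442. With a pseudocount of 5 the 2-fold counts were 482 and 476 between 2 and 4 h and 484 and 454 between 2 and 6 h; with one of 0.1 they were 2222 and 1860, and 2192 and 1792.

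**Figure D3:**
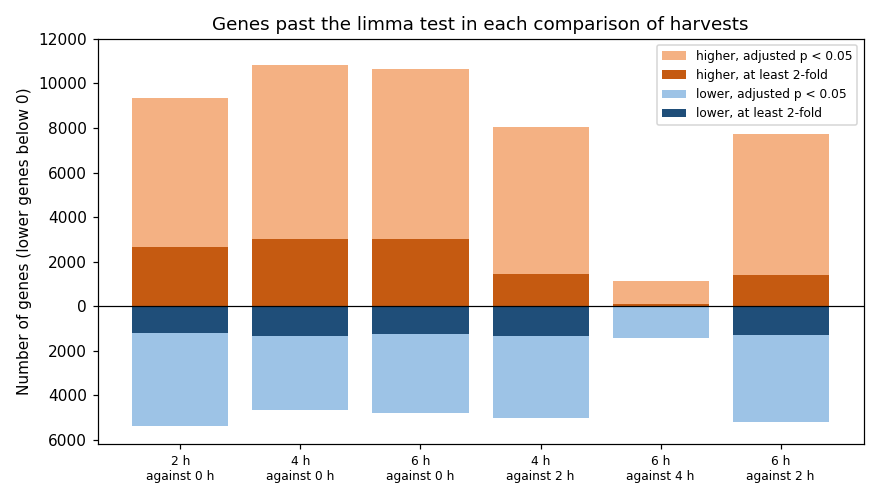
Number of genes higher (above 0) and lower (below 0) in each comparison of harvests, at a limma adjusted p under 0.05 (light) and also at least 2-fold (dark). The comparison of 6 h with 4 h holds 2561 genes, against 13065 for 4 h with 2 h.

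The genes changed 2-fold or more by 2 h divided into several courses. Of the 2658 genes raised 2-fold or more at 2 h, 1295 (48.7%) fell back between 2 and 4 h, 625 (23.5%) rose further and 738 did not pass the test in that interval. At 6 h, 1461 of them (55%) were still at least 2-fold above 0 h, 574 were above it by less, 559 did not pass the test and 64 were below the 0 h level. Their median log2 change was 1.47 at 2 h, 1.15 at 4 h and 1.17 at 6 h. Of the 1221 genes lowered 2-fold or more at 2 h, 629 (51.5%) rose again between 2 and 4 h, 129 fell further and 463 did not pass the test. At 6 h, 592 of them (48.5%) were still at least 2-fold below 0 h, and 69 were above it. These numbers depend on the pseudocount. With 5, the raised genes divided into 573 that fell back, 314 that rose further and 188 that did not pass the test, and 582 were still at least 2-fold above 0 h at 6 h. With 0.1 these were 1511, 824, 1591 and 2446, so that genes without a call outnumbered those that fell back. The lowered genes that rose again numbered 253 with 5 and 946 with 0.1, those that fell further 60 and 173, and those that did not pass the test 131 and 649. Median-ratio scaling gave 207 that fell further. With the 2 pseudocounts, 212 and 801 lowered genes were still at least 2-fold below 0 h at 6 h. Genes that ended on the opposite side numbered 25 and 21 with 5, and 93 and 123 with 0.1. Median-ratio scaling turned the balance of these genes, to 86 raised at 2 h and 52 lowered. Choosing genes by their change at 2 h favours high estimates at that harvest. In all, 1318 genes were raised and 529 lowered 2-fold or more at each of the 3 exposed harvests; a pseudocount of 0.1 gave 2240 and 703, and one of 5 gave 538 and 196.

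Most genes changed at 4 h did not pass the test between 4 and 6 h. Of the 3034 genes raised 2-fold or more at 4 h, 2253 (74.3%) did not pass the test between 4 and 6 h, 478 fell back and 303 rose further. For the 1323 lowered genes these numbers were 1142, 123 and 58. With a pseudocount of 5, 700 of 1275 raised and 378 of 480 lowered genes did not pass the test, and with 0.1 they were 3634 of 4346 and 1560 of 1779. Log2 changes against 0 h correlated across genes at r = 0.65 between 2 and 4 h and at r = 0.94 between 4 and 6 h. These comparisons share the 0 h libraries, and 20 simulations with unchanged exposed harvests gave r = 0.50 for each of these pairs. The covariance was 0.481 between 2 and 4 h and 0.745 between 4 and 6 h, where the simulations gave 0.0219 for each. Genes raised at both 2 and 4 h numbered 6739, where independent lists would share 3923, and genes lowered at both numbered 2921 against 970. For 4 and 6 h these overlaps were 9392 against 4475 and 3901 against 863. Part of each excess may come from the shared 0 h libraries. The simulations cannot size this part, since with unchanged harvests few calls could arise, and at most 0.05 genes were shared on average. Genes called in opposite directions numbered 1168 between 2 and 4 h and 62 between 4 and 6 h.

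**Figure D4:**
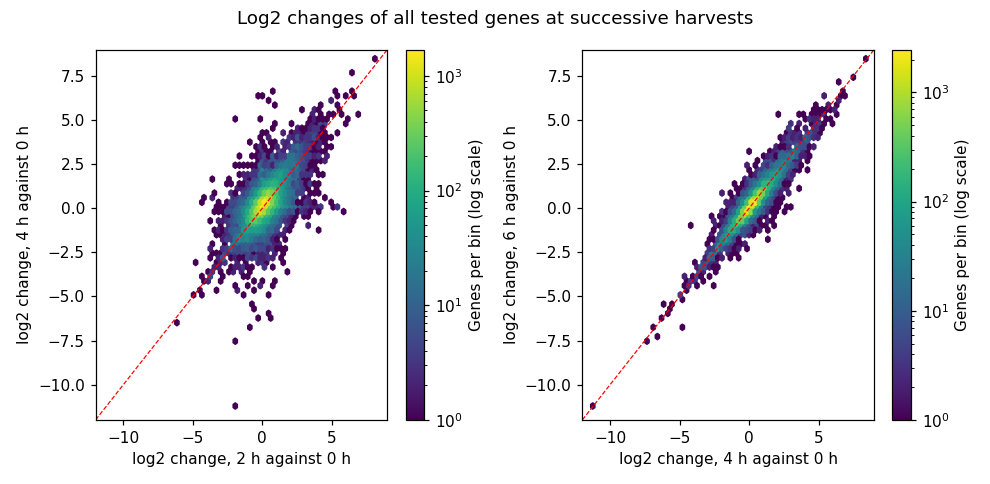
Log2 changes against 0 h of the 25841 tested genes at 2 and 4 h (left, r = 0.65) and at 4 and 6 h (right, r = 0.94), binned by number of genes on a log colour scale; the dashed line marks equal change. Genes scatter widely around the line between 2 and 4 h and lie near it between 4 and 6 h.

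The most abundant transcripts took a smaller part of the total at the exposed harvests. The 10 highest genes of each library held 20.6% ± 0.17 (SD, n = 3) of the summed values at 0 h, 15.8% ± 0.139 at 2 h, 14.8% ± 0.265 at 4 h and 14.7% ± 0.127 at 6 h, without overlap between 0 h and any later harvest (exact permutation test, two-sided p = 0.1, the smallest possible). The gene with the highest value in every library fell from 65629 ± 1140 (SD, n = 3) at 0 h to 44877 at 2 h and 37414 ± 527 at 6 h (log2 change -0.81, limma adjusted p = 5.79e-10). The gene second in mean value over all libraries fell from 41842 ± 603 to 28923 ± 595 at 6 h (log2 change -0.53, limma adjusted p = 8.42e-09). The third gene by mean value rose from 204.4 ± 6.57 at 0 h to 12525 at 2 h, 61.3-fold, and stood at 14665 ± 208 at 6 h (log2 change 6.16, limma adjusted p = 1.37e-14). These genes were picked after their values were seen. Among the 100 genes of highest mean, 32 were higher and 59 lower at 6 h, and 28 and 67 with median-ratio scaling. Genes changed 2-fold or more, in either direction, made up 29% of these 100 genes at 2 h and 24% at 6 h and 27.9% and 21.7% of the next 900. With median-ratio scaling the shares were 34% and 38% of the 100 genes and 25.8% and 24.3% of the next 900, and the 2-fold balance of the 100 genes at 6 h turned from 17 higher and 7 lower to 15 and 23. Among the 10841 tested genes of lowest mean value, 15.5% changed 2-fold or more at 2 h and 17.7% at 6 h. These shares cannot be compared with those of abundant genes, as log2(value + 1) understates changes of genes with low values. With a pseudocount of 0.1, the 2-fold counts of all tested genes at 2 h rose from 2658 and 1221 to 3926 and 1768. The shares by abundance were not computed with it.

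Some genes went from present to near 0 or the reverse. Between 0 and 2 h, 68 genes near 0 in all 3 libraries of the first harvest were at 5 or more in all 3 of the second, and 28 took the opposite course. These numbers were 31 gained and 46 lost between 2 and 4 h, and 1 gained and 1 lost between 4 and 6 h. With a minimum of 20 in place of 5 they were 12 and 1, 6 and 13, and 0 and 0. By course, 29 genes were near 0 at 0 h and present at each later harvest, 15 were present at 0 and 2 h and near 0 at 4 and 6 h, and 9 were near 0 at 0 and 2 h and present at 4 and 6 h. A further 12 genes were present at 0 h and near 0 at each later harvest, 12 were present at 2 h and near 0 at the other 3 harvests, and 6 were near 0 at 2 h and present at the other 3. Read depth behind these values is unknown, and a value of 0 can also be a failed estimate. The moderated F test over all harvests called 19512 genes (75.5%), of which 6593 differed 2-fold or more from 0 h at some harvest.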

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

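The tests of the spread, of gene copies differing between plants and of the share of the 10 highest genes were chosen after the results were seen; the tests of reads moving between copies and of other splits were set before their results were seen.

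Expression differed between harvests, by the test of the difference itself. It did so for 13065 genes between 2 and 4 h, for 12898 between 2 and 6 h and for 2561 between 4 and 6 h. Among genes raised 2-fold or more at 2 h, 64 were below their 0 h level at 6 h, and among genes lowered 2-fold or more at 2 h, 69 were above it. With median-ratio scaling these numbers were 86 and 52. Of the named genes, CTI12_AA422800 changed by 1.04, CTI12_AA498370 by -9.30 and CTI12_AA508840 by -5.67 on the log2(value + 1) scale between 2 and 4 h; the last, listed at 0 at 4 h, changed by -8.96 with a pseudocount of 0.1 and by -3.46 with 5. With a pure stop of transcription at 2 h, the course of CTI12_AA498370 from 2 to 4 h would need a transcript half-life of at most 12.7 min. Its fall from 0 to 2 h corresponds to 65.4 min if transcription stopped at 0 h. A stop after 0 h would give a shorter half-life, so these values do not show a change in decay.

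The first pattern is the small spread within a harvest, a median of 1.39% at 0 h for genes above 1000, although each library is described as a separate mix of seedlings. A candidate explanation is that the libraries of a harvest came from 1 RNA pool, in which case the tests would measure technical error and the calls would describe 4 pools and not 4 conditions. How much of the 1.39% is counting error is unknown, as no count and no other known technical repeat was at hand. A shared pool and separate pools of very even plants therefore cannot be told apart. Against a single pool at 2 h stands replicate 1, which spread by 7.11% and 8.47% from the other libraries, although a library made separately from the same RNA can also differ so.

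The second pattern is the genes present in one harvest and near 0 in another, 96 between 0 and 2 h and 77 between 2 and 4 h. If gene copies differed between plant pools, 1 pool for each harvest, 6 h against 4 h should have shown a like number, but it showed 2 genes, 2.08% of the number at 2 h against 0 h, which argues against that explanation unless the 4 and 6 h leaves came from the same plants. Copies differing between seedlings, with separate seedlings in each library, should give as many in any grouping, but of 100 splits of the 12 libraries the real one gave 468 over all pairs of harvests and the others a median of 6 (highest 456, mixing only 4 and 6 h); they stay open only for genes that differ between single libraries, of which pairs within a harvest showed 36.8% as many (87.25 against 237.2) as pairs between harvests. Of 458 genes present in one library and near 0 in another of the same harvest, 118 had a partner with opposite deviations of like size. This number lay within what 20 shuffles of the libraries gave (mean 115.1, highest 126). It argues against reads moving between pairs of near-identical copies as a general cause. Reads moving among more copies, or with deviations of unlike size, would have escaped this test. The ratio of 0.584 between these 118 genes and the 202 with a partner moving the same way decides nothing. Genes high in one library resemble each other by construction. A response to UV-B and a change with the hour of the day stay open, untested for want of unexposed plants.

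The third pattern is the excess of higher over lower genes, with a median log2 change of 0.198 at 6 h. As values lie near a fixed total, the fall in the summed share of each library's 10 highest genes may lift all others. The test left out the 10 genes of highest mean over all libraries, of which 5 were lower and 4 higher at 6 h. Without these genes and after rescaling, the median was still 0.144, so they account for only part of the shift. A broader fall of abundant transcripts and a wider set of active genes remain possible, and normalised values cannot show whether total RNA per cell changed.

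For each pair of harvests, the 10 splits of its 6 libraries are too few for a share under 0.05; the real split was the highest in each (1 of 10), with 13858 genes for 2 h against 0 h (highest other 1), 15368 for 4 h against 0 h (highest other 0), 15063 for 6 h against 0 h (highest other 0), 12245 for 4 h against 2 h (highest other 1), 2243 for 6 h against 4 h (highest other 5) and 11773 for 6 h against 2 h (highest other 2), in models of these 6 libraries alone. Splits of all 12 libraries into 4 groups can exclude chance only for independent libraries, and not if each harvest was 1 RNA pool. Of 100 such splits, only the real one (1 of 100) reached 19512 genes, which excludes chance if the libraries are independent. The highest other gave 18143 and mixed only libraries of 4 and 6 h, the harvests that differ least; the next gave 10056 and kept the 0 and 4 h harvests whole, 4 more gave 3175 to 5362, and the median of all splits but the real one was 1.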

How the results depend on the processing

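The number of genes called in each of the 6 comparisons of harvests stayed within 1.5 times its main value, with the same direction in the majority, under the replicate block, both other pseudocounts, no filter, limma without trend or robust estimation and models of only the 2 harvests; rescaling without the 10 highest genes, chosen after seeing the data, did so too. The count at any time, which has no direction, stayed within this bound under those run for it, all but the models of only 2 harvests. Median-ratio scaling kept the counts but brought the share of higher genes near 50% in each comparison, by construction. Of the 15441 genes called at 6 h against 0 h it called 12271. The replicate block gave 14415, 15228 and 15179 genes at 2, 4 and 6 h against 0 h and 2203 at 6 h against 4 h. Same-numbered libraries deviated together at r = -0.025 to 0.043 over 18 pairs, and 2 of 12 libraries correlated best with their own number. No effect of the replicate number was seen, although a pairing with little effect on the values cannot be excluded. Requiring a fold of at least 2 as well cut the counts, by construction, to 3879 at 2 h, 4357 at 4 h and 4263 at 6 h against 0 h, to 2782 at 4 h and 2693 at 6 h against 2 h, to 158 at 6 h against 4 h and to 6593 at any time. Leaving out each library in turn gave 13493 to 13760 genes at 2 h, 14287 to 14467 at 4 h and 14252 to 14488 at 6 h against 0 h, 11732 to 12460 at 4 h and 11619 to 12209 at 6 h against 2 h, 1726 to 1926 at 6 h against 4 h and 18571 to 19115 at any time, fewer in part because fewer libraries were fitted. The log2 changes of the named genes kept their side of the threshold and, where called, their direction in 220 of 220 alternative values. As these genes were picked for the largest changes in the same data, their stability says little about other genes. Of 684 alternative counts of time-course groups, all computed after seeing the data, 45 moved by over 1.5 times, 33 with a pseudocount of 5, 11 with one of 0.1 and 1 (genes lowered at 2 h that fell further by 4 h, 207) with median-ratio scaling, mostly because the 2-fold bound on log2(value + pseudocount) admits more low genes as the pseudocount shrinks. The alternatives for count data did not apply and those for the 27 gene lists were not run, as no gene names were at hand. Unknown depth limits what can be said of genes listed at 0 and of the unit.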

Other observations

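The test of neighbouring identifiers was set before its result was seen. Identifiers in the table run in steps of 10, and 11709 pairs of tested genes are neighbours in this numbering; whether the numbering follows the genome is not stated. The hypothesis that neighbours change together at 6 h was tested by the correlation of their log2 changes, r = 0.033. Of 10000 shuffles the highest gave 0.037, so the bound set beforehand, above all shuffles, was not met; the one-sided permutation p was 3e-04 and the relation, if any, was weak. Among neighbours that both changed 2-fold or more, 63.3% went the same way, where the overall balance of rises and falls gives 58.5%, and the number of such pairs, 338, lay within the shuffles (mean 318.8, highest 391).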
